A study of Homo sapiens with 6 samples.

How the data were processed

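RNA was sequenced from 6 libraries of MIA PaCa-2 cells, 3 treated with BP and 3 with BP+Huaier. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra kit and read as 150 bp pairs on a NovaSeq instrument. Per the submitters' processing notes, the tools were fastp 0.20.0, HISAT2 2.1.0 and featureCounts 1.6.1 and the build was GRCh38. The annotation release and the strand, multi-mapping and overlap settings of the counting are not given in the sources used here. The deposited values are whole-number counts per gene, not normalized, as read from the values, which sum to a different total in each library.

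The table held 60648 genes. Of these, 44 second copies on the Y chromosome of the pseudoautosomal genes, with 0 counts, were left out, and 60604 genes were used. The lines of 1 more gene, ANK2, were broken into 3 pieces and were not used, with at most 147 counts, or 0.00094% of a library (95% Wilson interval 0.00080 to 0.0011). Intervals and floors cover counting error only. Symbols were taken from a table of gene names, which matched 99.77% of the IDs. Biotypes and GC content of the longest transcript came from GENCODE release 29, which held 58336 of the genes. Coordinates are those of the deposited table, 1-based. Columns were mapped to samples by the sample titles.

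Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 15022, libraries were scaled by TMM, and BP+Huaier was compared with BP by the robust quasi-likelihood test with group as the only term. Calls used a Benjamini-Hochberg adjusted p under 0.05. CPM values of genes are scaled by TMM and given as mean ± SD over 3 libraries, and sums over transcript classes, nuclear copies and olfactory receptor genes are scaled by the total counts of the library unless TMM is named, and log2 fold changes carry the standard error implied by the test. The common biological coefficient of variation was 18.1%. Within the BP group, counts of libraries differed by 3.74 to 10.0 times the sampling variance, and within the BP+Huaier group by 16.8 to 75.5 times, more than counting error alone would give, and all were counted separately. Repeat preparations of 1 RNA can also differ by more than counting error, so this does not show separate cultures.

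The 22 pathway lists and the 9 lists of cell type markers and RNA quality were fixed before the data were examined, as were the design, the other settings tried and the rule for named genes. Lists were tested with camera from limma 3.58.1 (correlation 0.01, two-sided, adjusted within each family) where at least 3 members were measured, beside camera with an estimated correlation and fry, which asks whether members move on balance one way and compares them with no other genes. The rule named the 8 largest rises and falls among protein-coding genes with an adjusted p under 0.05, at least 5 CPM on average and no overlap between groups. It also named, for the autophagy and mitophagy lists and each called pathway list, the 3 called members of at least 5 CPM with the largest change, and always PINK1, BNIP3, BNIP3L, SQSTM1, MAP1LC3B, BECN1 and LAMP1. Of the genes the rule names and of the pathway lists, 1 each is not reported here, though both enter the counts. Other members named in the text, where 5 or fewer of a list moved one way or as examples, were chosen after their values were seen.

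Alternatives were DESeq2 size factors, scaling by library size alone, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 5 CPM, protein-coding genes only, the replicate number as a block, each library left out in turn, and an adjusted p under 0.01. Removal of a spline trend on GC content and length in each library was added after seeing the data. Another pseudocount was not tried because the values were counts. The steps were tested on simulated counts with the means and dispersions of these libraries. Of 14656 simulated genes for this comparison, 100 changed 2-fold were recovered at 55% and 100 changed 4-fold at 95%, and 8.54% of the calls were false. A simulated GC trend gave 3215 calls before and 0 after removal by edgeR. Apart from the planted changes, both simulated groups shared a mean and dispersion per gene, and the trend was the same in every BP+Huaier library. The real groups differed in spread and the real libraries in GC trend, so these rates need not hold for the real comparison. Similarity of nuclear copies to mitochondrial transcripts was computed with blastn 2.17.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.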

Results

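Gene expression was measured by RNA sequencing in MIA PaCa-2, an established human pancreatic carcinoma cell line. The cells were treated with black phosphorus (BP), a layered form of elemental phosphorus, at 12.5 µg/ml, or with BP at 12.5 µg/ml together with Huaier, an extract of a medicinal fungus, at 10 mg/ml. Each group held 3 libraries. Total counts on genes were 16547822, 17036565 and 15657593 in the BP libraries and 16856727, 15808056 and 16733871 in the BP+Huaier libraries. At these depths 3 counts corresponded to between 0.160 and 0.222 CPM (counts scaled to the size of the library, with TMM factors). The treatment time is not given in the sources used here, and cells without BP were not analysed here. The comparison asks which transcripts differed when Huaier was added to BP, with autophagy and mitophagy, the removal of cell components and of mitochondria through lysosomes, named as the processes of interest. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The fit shared a dispersion per gene between the groups, although the spread was larger within BP+Huaier. No fit with a separate spread for each group was run, so p-values may be off where the spreads differ.

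With Huaier added, 28 of 29 immediate early genes rose, among them DUSP2, NR4A1, FOSB and FOS, as did 19 of 24 genes of cholesterol synthesis, 21 of 33 antioxidant genes regulated by NRF2 and 13 of 47 genes of DNA replication and G1/S, whereas 18 of 38 interferon-stimulated genes fell. These 5 lists were called by camera with a preset correlation, and adjusted p = 0.16, 0.16, 0.18, 0.23 and 0.10 with an estimated correlation, in that order. Without BP 1, 2 and 3, immediate early rises numbered 26, 25 and 25, and cholesterol synthesis rises 13, 12 and 15. NRF2 rises then numbered 5, 6 and 7, G1/S rises 3, 4 and 5, and interferon falls 11, 11 and 11. Of 15022 genes tested, 2160 were higher and 2246 lower in BP+Huaier at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 2014 of these 4406 changed at least 2-fold, 664 of them higher and 1350 lower. Of 12459 protein-coding genes tested, 2065 were higher and 1600 lower, which is the background for the list counts given here. Of the 47 G1/S members 32 were not called. Among tested genes outside the protein-coding class, which include genes without a biotype in GENCODE, 95 were higher and 646 lower. The values of the groups did not overlap for 7035 genes, or 46.8% of those tested, where chance gives 10%. Scaling by library size alone gave 1051 higher and 2959 lower genes, 26.2% of calls higher instead of 49.0%, and moved the median log2 fold change of all genes from -0.02 to -0.28.

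Single libraries moved the number of calls. Without BP+Huaier 3 there were 4452 higher and 4793 lower genes, and 3542 past 2-fold. Without BP 1 there were 810 higher, 909 lower and 1301 past 2-fold. The corresponding numbers were 834, 938 and 1285 without BP 2, and 1021, 1056 and 1494 without BP 3. Without BP+Huaier 2 they were 952, 1015 and 1294, and without BP+Huaier 1 they were 1775, 1845 and 1797. Of the 293 called members of the gene lists, 155, 147 and 140 were not called without BP 1, 2 and 3, and 59, 136 and 0 without BP+Huaier 1, 2 and 3. BP+Huaier 3 stood apart from the other libraries of its group. On the first principal component, with 72.4% of the variance, it lay at 11.5, while BP+Huaier 1 and 2 lay at 65.1 and 66.0 and the BP libraries between -50.5 and -43.4. The libraries also differed by transcript GC content, within the groups as well as between them. Across 13507 genes, which are not independent replicates, the log2 ratio to the BP mean correlated with GC content at r = 0.46 in BP+Huaier 1, 0.32 in BP+Huaier 2 and 0.04 in BP+Huaier 3. Against the other BP libraries, BP 1 gave r = 0.03, BP 2 gave r = -0.51 and BP 3 gave r = 0.50. The median GC content was 56.6% for higher genes, 46.4% for lower genes and 49.4% for all tested genes. After a trend on GC content and length was removed in each library, 90.2% of the higher and 92.5% of the lower calls were kept. With genes newly called, 2930 were then higher and 2866 lower, more than before removal.

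**Figure D1:**
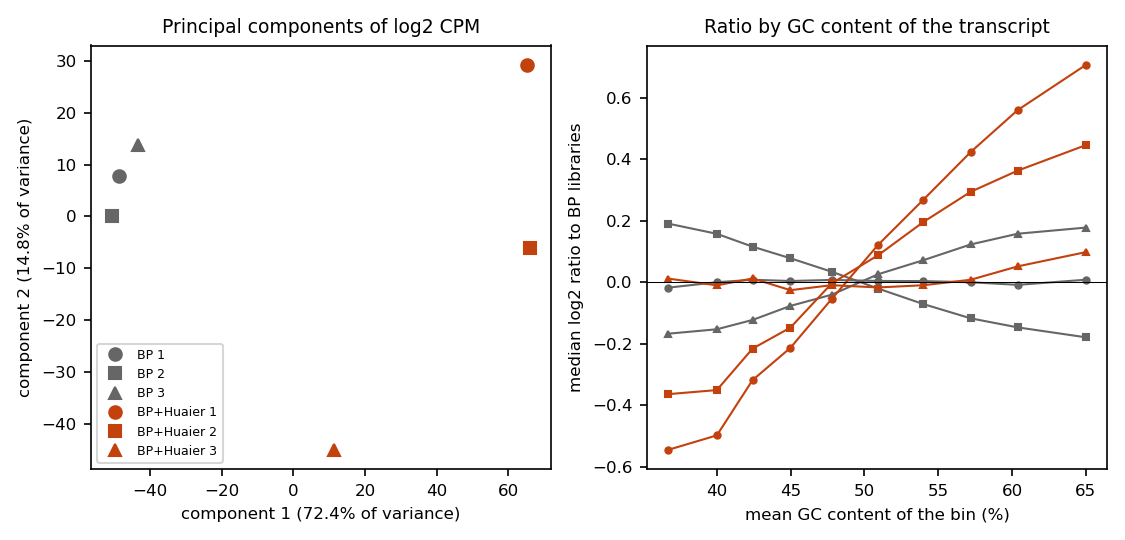
Left, the 6 libraries on the first and second principal components of log2 CPM (axes in component units, with the percent of variance); right, the median log2 ratio of each library to the BP libraries in 10 bins of transcript GC content (horizontal axis in percent; a BP library is set against the other BP libraries). BP+Huaier 3 lies at 11.5 on the first component, and in the bin of highest GC content the ratio was 0.71 in BP+Huaier 1, 0.45 in BP+Huaier 2 and 0.10 in BP+Huaier 3.

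The 8 largest rises among well-expressed protein-coding genes were DUSP2, NR4A1, FOSB, DUSP1, CDKN1C, GDF15, FOS and ZFP36, with folds from 20.8 down to 10.8. DUSP2 (ENSG00000158050.5, GRCh38 chromosome 2, 96143169 to 96145440), a phosphatase that inactivates MAP kinases, went from 7.72 ± 0.68 to 161 ± 162 CPM (SD, n = 3), a log2 fold change of 4.38 ± 0.67 (SE; edgeR adjusted p = 0.0030). NR4A1 (ENSG00000123358.20, chromosome 12, 52022832 to 52059507), a nuclear receptor induced early by many stimuli, rose 18.9-fold, from 3.31 ± 0.36 to 62.7 ± 31.5 CPM. The AP-1 subunits FOSB and FOS rose 15.6-fold and 12.4-fold, and the MAP kinase phosphatase DUSP1 rose from 40.2 ± 1.19 to 524 ± 384 CPM. CDKN1C, a cyclin-dependent kinase inhibitor, rose 12.5-fold, from 10.6 ± 1.44 to 133 ± 88.2 CPM. GDF15, a secreted stress-induced cytokine, rose 12.5-fold, from 6.24 ± 0.71 to 78.0 ± 46.3 CPM. ZFP36, which promotes decay of AU-rich transcripts, rose 10.8-fold. All 8 were higher in 3 of 3 BP+Huaier libraries than in any BP library, but the naming rule required this and a passed test. Their edgeR adjusted p lay between 0.00062 and 0.0080, and each had its highest value in BP+Huaier 2. Without that library the folds were 8.89 for DUSP2, 8.51 for FOSB, 7.64 for DUSP1, 7.93 for CDKN1C and 4.39 for FOS, each still called. With limma-voom the fold of FOS was 8.0.

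The 8 largest falls were NEK10, IQCN, MUC6, RBPMS, PRMT6, TTN, ZFHX2 and UBAP1L, lower by 26.7-fold to 5.45-fold. NEK10 (ENSG00000163491.16, chromosome 3, 27110085 to 27369460), a kinase of the NIMA family, went from 10.7 ± 0.33 to 0.37 ± 0.37 CPM (SD, n = 3), a log2 fold change of -4.74 ± 0.50 (SE; edgeR adjusted p = 8.9e-04). IQCN (ENSG00000130518.17, chromosome 19, 18257097 to 18274509) went from 36.7 ± 2.17 to 1.58 ± 0.39 CPM, with an edgeR adjusted p of 5.0e-05, and MUC6, a gel-forming mucin, from 8.90 ± 1.22 to 0.63 ± 0.60 CPM. PRMT6 (ENSG00000198890.9, chromosome 1, 107056674 to 107067636), an arginine methyltransferase, was 6.01-fold lower, from 18.5 ± 0.30 to 3.09 ± 0.68 CPM, and RBPMS, an RNA-binding protein, was 7.63-fold lower. TTN, ZFHX2 and UBAP1L were lower by 5.62-fold, 5.61-fold and 5.45-fold. TTN exons overlapped those of the antisense gene TTN-AS1 over 14004 bases. Without BP+Huaier 3 the falls were larger, 56.7-fold for NEK10, 29.96-fold for MUC6 and 9.37-fold for TTN, and after the GC and length trend was removed the fall of TTN was 3.05-fold. With limma-voom NEK10 was 46.1-fold lower. In BP+Huaier 1 and 2 NEK10 was at 0 and 0.37 CPM and MUC6 at 0.28 and 0.30 CPM. There 3 counts corresponded to 0.21 and 0.22 CPM, so the sizes of the falls of NEK10 and MUC6 are uncertain.

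**Figure D2:**
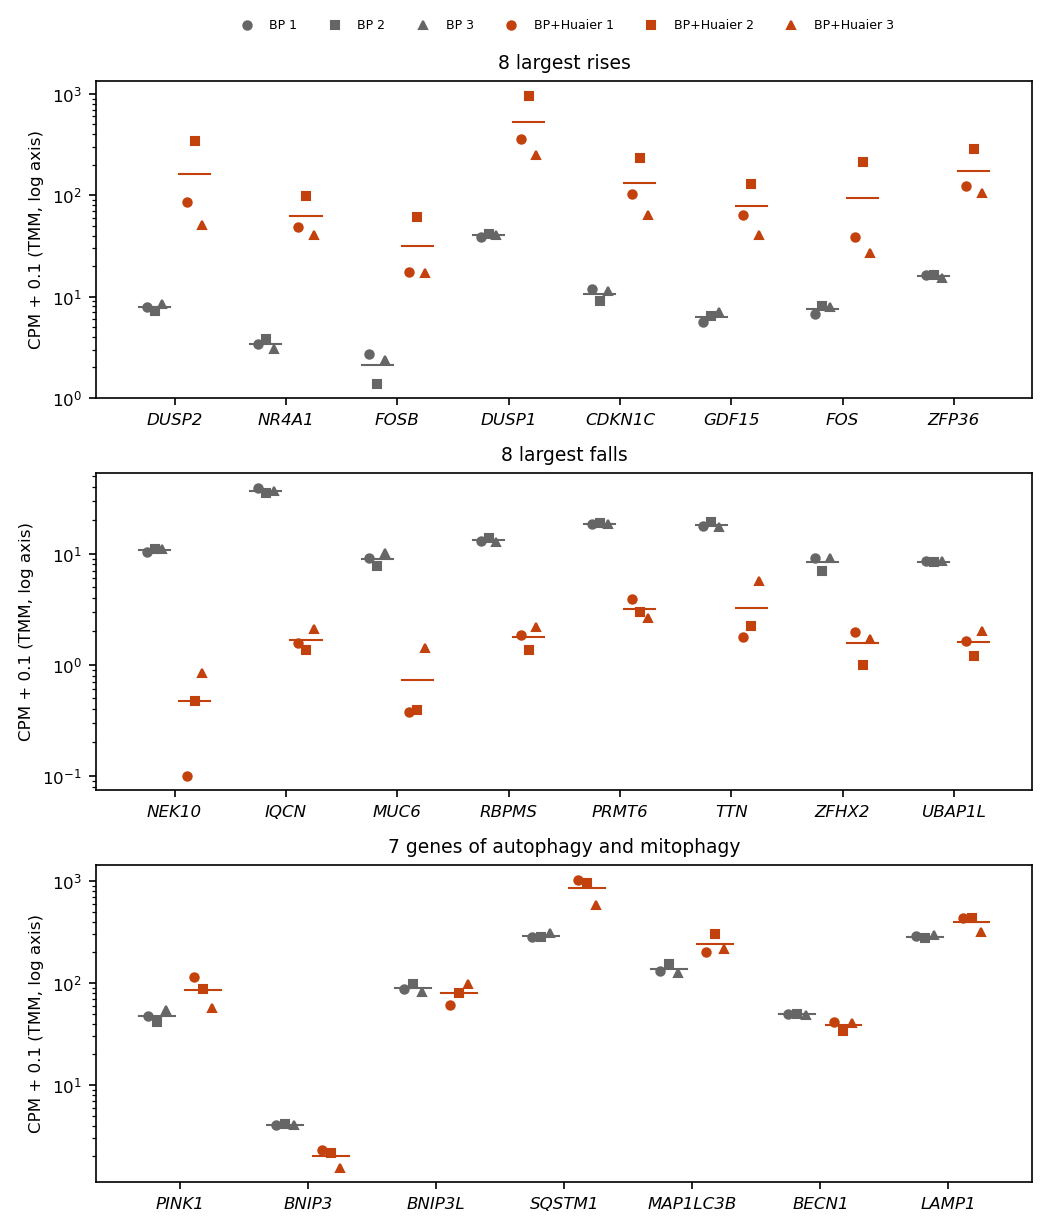
Normalized expression (CPM with TMM scaling, plus 0.1, log axis) of the 8 largest rises, the 8 largest falls and 7 genes of autophagy and mitophagy in each library, with bars at the group means (n = 3). The rises have their highest value in BP+Huaier 2, 347 CPM for DUSP2 against 85.1 and 50.9 CPM in the other BP+Huaier libraries, whereas SQSTM1 was 1027, 963 and 584 CPM in BP+Huaier 1, 2 and 3.

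In the autophagy core list MAP1LC3A and MAP1LC3B, which encode LC3 proteins of the autophagosome membrane, rose. MAP1LC3A rose 2.51-fold, from 20.8 ± 2.54 to 52.3 ± 16.1 CPM (SD, n = 3), and MAP1LC3B rose 1.75-fold, from 136 ± 14.4 to 239 ± 56.2 CPM. ATG101, a subunit of the ULK1 initiation complex, rose 2.69-fold, from 12.4 ± 1.18 to 33.3 ± 9.62 CPM. PIK3C3, the lipid kinase that starts autophagosome nucleation, was the member that fell, 2.20-fold, from 43.6 ± 3.79 to 19.7 ± 7.92 CPM. BECN1, its partner, was at 49.1 ± 0.08 and 38.4 ± 4.05 CPM and did not pass the test (edgeR adjusted p = 0.077), with 300 exon bases overlapping PSME3 on the opposite strand. Of 40 measured members 13 rose, 1 fell and 26 did not pass, with 13 and 1 when adjusted over the list alone. The list as a whole was not called (camera, median log2 fold change 0.13, adjusted p = 0.082, range 0.0030 to 0.54 over 18 alternatives; adjusted p = 0.20 with an estimated correlation). Without BP+Huaier 1 the camera adjusted p was 0.040, and it was 0.039 after the GC and length trend was removed. The MAP1LC3B call was lost without BP 1 (edgeR adjusted p = 0.065) and without BP 3 (0.062), and the PIK3C3 call without BP 2 (0.059) and without BP+Huaier 2 (0.061). BECN1 was called lower without BP+Huaier 3 (0.012), with scaling by library size alone (0.028) and with genes of at least 5 CPM (0.041), in a range of 0.012 to 0.28 over 15 alternatives. Rises in the autophagy core list numbered 3, 6 and 4 without BP 1, 2 and 3, and 11, 5 and 17 without BP+Huaier 1, 2 and 3. Falls numbered 12 without BP+Huaier 3.

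Genes of the mitophagy list went both ways. SQSTM1 (ENSG00000161011.20, chromosome 5, 179806398 to 179838078), the p62 adaptor that links ubiquitinated cargo to autophagosomes, rose 2.95-fold, from 291 ± 17.8 to 858 ± 239 CPM (SD, n = 3), a log2 fold change of 1.56 ± 0.22 (SE; edgeR adjusted p = 0.0021). PINK1 (ENSG00000158828.8, chromosome 1, 20633458 to 20651511), the kinase that marks damaged mitochondria, rose 1.79-fold, from 47.9 ± 6.42 to 86.0 ± 28.96 CPM (edgeR adjusted p = 0.030). MFN1, a mitochondrial fusion GTPase, fell 1.81-fold, from 55.9 ± 4.96 to 30.9 ± 8.97 CPM, and the mitophagy receptor BNIP3 fell 2.09-fold, from 3.99 ± 0.05 to 1.92 ± 0.42 CPM. AMBRA1, a regulator of autophagy, rose 1.49-fold and the deubiquitinase USP8 fell 1.64-fold. BNIP3L, a further mitophagy receptor, was at 89.1 ± 8.86 and 79.0 ± 18.2 CPM (edgeR adjusted p = 0.49). Of 36 members 3 rose, 3 fell and 30 did not pass, with 3 and 2 when adjusted over the list alone. After the GC and length trend was removed 10 rose and 2 fell by edgeR (camera adjusted p = 0.079). In the main fit 4406 of all 15022 tested genes were called, so the list did not hold an excess of calls. The list was not called (camera, median 0.16, adjusted p = 0.24, range 0.023 to 0.58 over 18 alternatives; adjusted p = 0.30 with an estimated correlation).

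Several of these calls changed when 1 library was left out. The PINK1 call was lost without BP 1, BP 2 or BP 3 (edgeR adjusted p = 0.095, 0.12 and 0.066), without BP+Huaier 1 or 2 (0.064 and 0.094) and with scaling by library size alone (0.073). The MFN1 call was lost without BP 1, BP 2, BP 3 or BP+Huaier 2 (0.051, 0.080, 0.056 and 0.074), and the BNIP3 call without BP 1, BP 2 or BP 3 (0.061, 0.062 and 0.058). BNIP3L was called lower without BP+Huaier 3 (0.032). The AMBRA1 call was lost without each BP library and without BP+Huaier 2 (edgeR adjusted p up to 0.10), and the USP8 call without every library but BP+Huaier 3 (up to 0.17). Rises in the mitophagy list numbered 1, 1 and 1 without BP 1, 2 and 3, and 2, 1 and 15 without BP+Huaier 1, 2 and 3. Falls in the mitophagy list numbered 0, 0 and 0 without BP 1, 2 and 3, and 2, 1 and 7 without BP+Huaier 1, 2 and 3. The exons of PINK1 overlapped those of PINK1-AS on the opposite strand over 39.5% of their bases, and the exons of SQSTM1 overlapped MRNIP over 21.0%. Whether the counting used strand is not given, so these values are uncertain to that extent.

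Of the lysosomal genes 12 of 50 rose. CTSL, which encodes the protease cathepsin L, rose 2.39-fold, from 143 ± 4.85 to 341 ± 15.0 CPM (SD, n = 3), and the transcription factors of lysosome genes TFE3 and TFEB rose 1.98-fold and 1.85-fold. Of 50 members 12 rose and 0 fell by edgeR, with 11 rises when adjusted over the list alone (camera median 0.29, adjusted p = 8.3e-04; adjusted p = 0.38 with an estimated correlation). LAMP1, a lysosomal membrane protein, was at 284 ± 9.29 and 393 ± 66.9 CPM and missed the threshold (edgeR adjusted p = 0.052), which it passed without BP+Huaier 3 (2.7e-05), with DESeq2 size factors (0.048), by DESeq2 (0.016), with no filter on low counts (0.021) and after the GC and length trend was removed (0.024), in a range of 2.7e-05 to 0.18 over 15 alternatives. The TFEB call was lost without BP 1, BP 2 or BP 3 (0.094, 0.088 and 0.083), without BP+Huaier 1 or 2 (0.058 and 0.084) and with scaling by library size alone (0.069). Rises in the lysosome list numbered 3, 4 and 5 without BP 1, 2 and 3, and 6, 5 and 29 without BP+Huaier 1, 2 and 3, and 3 members fell without BP+Huaier 3.

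Immediate early genes, which respond to growth factors and stress without new protein synthesis, rose almost throughout. Of 29 measured members 28 rose, with KLF4 the exception (28.4 ± 3.69 and 40.3 ± 9.82 CPM, edgeR adjusted p = 0.080), and 29 when adjusted over the list alone. Next to DUSP2, NR4A1 and FOSB, EGR1 went from 82.8 ± 1.37 to 437 ± 77.4 CPM (SD, n = 3). The median log2 fold change of the list was 1.87 (camera adjusted p = 2.2e-27; adjusted p = 0.16 with an estimated correlation), and it was 1.61 after the GC and length trend was removed.

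In the list of the integrated stress response 17 of 33 members rose. DDIT3, the transcription factor CHOP, rose 10.0-fold, from 7.45 ± 0.82 to 74.6 ± 38.3 CPM (SD, n = 3), and ATF3 rose 5.24-fold, beside GDF15. Of 33 members 17 rose and 1, WARS1, fell (18 and 1 adjusted over the list alone; camera median 0.60, adjusted p = 3.5e-08; adjusted p = 0.16 with an estimated correlation). DDIT3 shared 355 exon bases with MARS1 on the opposite strand, where MARS1 had a log2 fold change of 0.30 (edgeR adjusted p = 0.19). The WARS1 call was lost without each BP library and without BP+Huaier 2 (up to 0.099), and 2 members fell without BP+Huaier 3. In the list of the unfolded protein response of the endoplasmic reticulum 13 of 29 members rose and 0 fell by edgeR (13 adjusted over the list alone; camera median 0.35, adjusted p = 1.8e-05; adjusted p = 0.20 with an estimated correlation). HERPUD1 rose 4.10-fold, the chaperone HSPA5 rose 2.98-fold, from 967 ± 15.2 to 2883 ± 1056 CPM, and DNAJB9 rose 2.62-fold. Rises in this list numbered 6, 7 and 7 without BP 1, 2 and 3, and 14, 7 and 20 without BP+Huaier 1, 2 and 3, and 2 members fell without BP+Huaier 3.

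Among heat shock genes DNAJB1, a co-chaperone of HSP70, rose 4.09-fold, from 303 ± 7.80 to 1239 ± 732 CPM (SD, n = 3). The near-identical HSP70 genes HSPA1A and HSPA1B rose 4.76-fold and 4.08-fold, values that are uncertain one by one because reads can be shared between them. Of 25 members 11 rose and 1, HSPA4L, fell (11 and 1 adjusted over the list alone; camera median 0.49, adjusted p = 0.0024; adjusted p = 0.39 with an estimated correlation), and fry did not call it (adjusted p = 0.085). The HSPA1A call was lost without BP 1, BP 2 or BP 3 (edgeR adjusted p = 0.052, 0.069 and 0.056), and so was that of HSPA1B (0.065, 0.081 and 0.065). Without BP+Huaier 2 their folds were 2.34 and 2.06. The HSPA4L call was lost without every library but BP+Huaier 3 (up to 0.15). Rises in heat shock genes numbered 2, 2 and 2 without BP 1, 2 and 3, and 7, 4 and 14 without BP+Huaier 1, 2 and 3. Among antioxidant genes regulated by NRF2, OSGIN1 rose 5.83-fold, HMOX1, heme oxygenase, rose 3.69-fold and AKR1C1, an aldo-keto reductase with close paralogs, rose 2.89-fold, from 165 ± 9.63 to 476 ± 37.8 CPM. Of 33 members 21 rose and 1, ABCC2, fell (23 and 2 adjusted over the list alone; camera median 0.66, adjusted p = 2.2e-07; adjusted p = 0.18 with an estimated correlation). OSGIN1 shared 457 exon bases with MLYCD, which lies on the same strand. The ABCC2 call was lost without BP 2 and without BP+Huaier 2 (edgeR adjusted p = 0.051 and 0.052). Rises in NRF2 genes numbered 5, 6 and 7 without BP 1, 2 and 3, and 18, 9 and 24 without BP+Huaier 1, 2 and 3, and 2 members fell without BP+Huaier 3.

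Of the genes of cholesterol synthesis 19 of 24 rose. INSIG1, a sensor protein that restrains SREBP processing, rose 4.19-fold, from 98.3 ± 10.7 to 412 ± 110 CPM (SD, n = 3), MSMO1, a sterol oxidase, rose 4.09-fold, and FDFT1, squalene synthase, rose 3.25-fold. Of 24 members 19 rose and 0 fell by edgeR (20 adjusted over the list alone; camera median 0.95, adjusted p = 1.7e-15; adjusted p = 0.16 with an estimated correlation). Among fatty acid synthesis genes FASN rose 2.30-fold, from 1398 ± 87.9 to 3219 ± 672 CPM, DGAT2 rose 2.23-fold and ACSS2 rose 2.04-fold. There 8 of 19 rose and 1, GPAM, fell (9 and 1 adjusted over the list alone; camera median 0.31, adjusted p = 0.0022; adjusted p = 0.16 with an estimated correlation). The GPAM call was lost without every library but BP+Huaier 3 (edgeR adjusted p up to 0.17). After the GC and length trend was removed 13 of the 19 fatty acid synthesis genes rose and 0 fell. Rises in cholesterol synthesis numbered 13, 12 and 15 without BP 1, 2 and 3, and 18, 14 and 21 without BP+Huaier 1, 2 and 3. Rises in fatty acid synthesis numbered 3, 3 and 3 without BP 1, 2 and 3, and 7, 3 and 12 without BP+Huaier 1, 2 and 3, and 2 members fell without BP+Huaier 3.

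**Figure D3:**
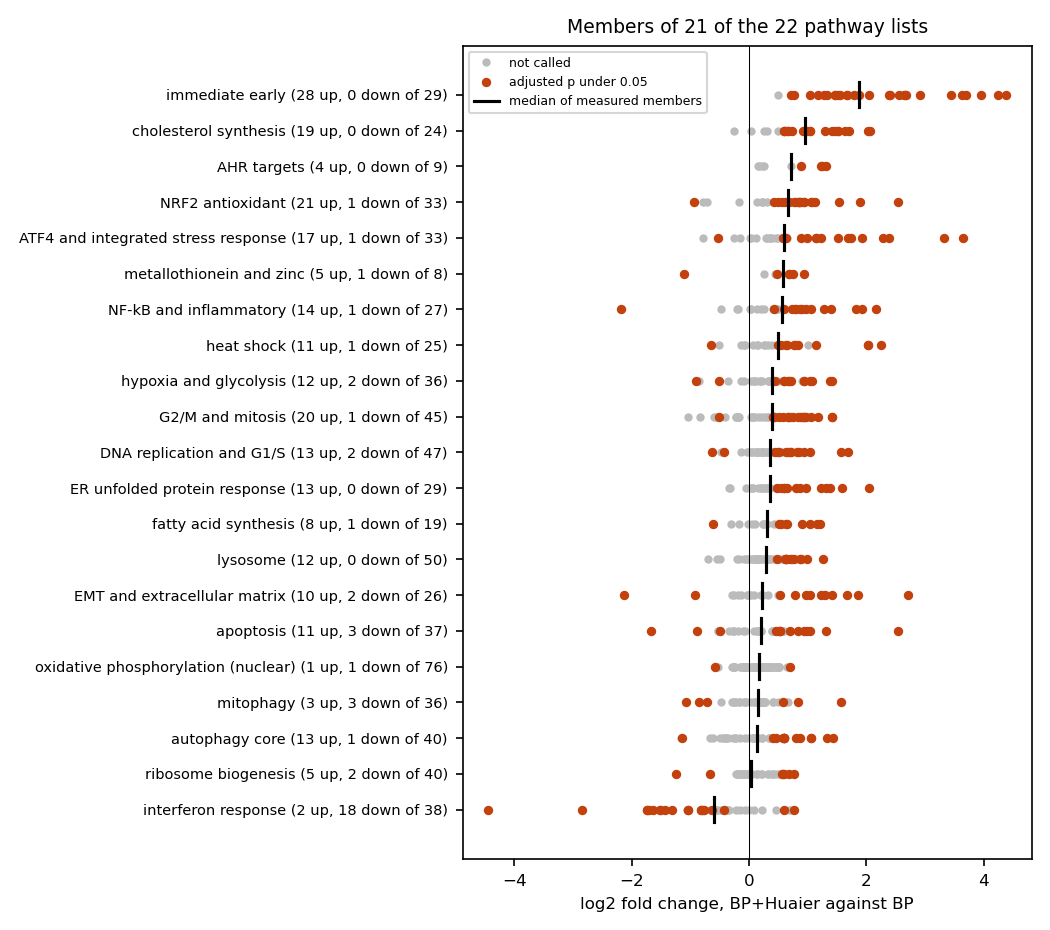
Log2 fold change (horizontal axis, BP+Huaier against BP, n = 3 libraries each) of every measured member of 21 of the 22 pathway lists, with members at an edgeR adjusted p under 0.05 in orange, others in grey and the median of each list as a black line. The immediate early list has the highest median, 1.87, and the interferon list the lowest, -0.60.

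Of the cell cycle lists, 13 of 47 and 20 of 45 members rose. In DNA replication and G1/S, RRM2, a subunit of ribonucleotide reductase, rose 3.22-fold, from 173 ± 8.75 to 558 ± 69.0 CPM (SD, n = 3), the licensing factor CDT1 rose 2.96-fold and E2F1 rose 2.06-fold. There 13 of 47 rose and 2, GINS4 and POLA1, fell (13 and 2 adjusted over the list alone; camera median 0.36, adjusted p = 7.4e-05; adjusted p = 0.23 with an estimated correlation). In G2/M and mitosis, HJURP, UBE2C and AURKB rose 2.67-fold, 2.66-fold and 2.25-fold. There 20 of 45 rose and 1, HMMR, fell (21 and 3 adjusted over the list alone; camera median 0.39, adjusted p = 7.4e-05; adjusted p = 0.17 with an estimated correlation). The GINS4 and POLA1 calls were lost without every library but BP+Huaier 3 (edgeR adjusted p up to 0.19 and 0.13), and the HMMR call without each BP library and without BP+Huaier 2 (up to 0.10). Rises in the G1/S list numbered 3, 4 and 5 without BP 1, 2 and 3, and 10, 4 and 31 without BP+Huaier 1, 2 and 3. Rises in the G2/M list numbered 11, 12 and 12 without BP 1, 2 and 3, and 15, 12 and 24 without BP+Huaier 1, 2 and 3. Falls in the G2/M list numbered 0, 0 and 0 without BP 1, 2 and 3, and 1, 0 and 14 without BP+Huaier 1, 2 and 3.

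The apoptosis list held genes that promote cell death among its rises and among its falls. The pro-apoptotic BBC3 and BAK1 rose 5.79-fold and 2.48-fold, the death ligand TNFSF10 fell 3.18-fold, from 9.52 ± 0.68 to 2.96 ± 1.123 CPM (SD, n = 3), the initiator caspase gene CASP8 fell 1.85-fold and CFLAR, which blocks it, fell 1.40-fold. Of 37 members 11 rose and 3 fell, with 11 and 3 when adjusted over the list alone (camera median 0.20, adjusted p = 0.029; adjusted p = 0.23 with an estimated correlation). This call was also lost with genes of at least 5 CPM (camera adjusted p = 0.24) and with protein-coding genes only (0.094). The CFLAR call was lost without each BP library and without BP+Huaier 2 (edgeR adjusted p up to 0.11). Rises in the apoptosis list numbered 5, 5 and 5 without BP 1, 2 and 3, and 9, 6 and 19 without BP+Huaier 1, 2 and 3, and 7 members fell without BP+Huaier 3.

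Of the interferon-stimulated genes 18 of 38 fell. OAS2, an RNA sensor of the oligoadenylate synthetase family, was 3.33-fold lower, from 23.6 ± 3.28 to 7.07 ± 1.33 CPM (SD, n = 3), and the antiviral ADP-ribosyltransferases PARP14 and PARP9 were 3.32-fold and 3.24-fold lower. Of 38 members 18 fell and 2, ISG20 and TAP1, rose (19 and 3 adjusted over the list alone; camera median -0.60, adjusted p = 2.0e-06; adjusted p = 0.10 with an estimated correlation). In the NF-kB and inflammatory list IER3 rose 4.49-fold, the cytokine LIF rose 3.78-fold and the chemokine CXCL8 rose 3.55-fold, from 66.2 ± 8.72 to 235 ± 65.8 CPM. There 14 of 27 rose and 1, ICAM1, fell (16 and 2 adjusted over the list alone; camera median 0.56, adjusted p = 3.8e-05; adjusted p = 0.23 with an estimated correlation). Falls in the interferon list numbered 11, 11 and 11 without BP 1, 2 and 3, and 16, 13 and 22 without BP+Huaier 1, 2 and 3, and 4 members rose without BP+Huaier 3. The TAP1 call was lost without every library but BP+Huaier 3, that of ISG20 without every library but BP 3 and BP+Huaier 3, and that of ICAM1 without BP 1, BP 3 or BP+Huaier 2 (edgeR adjusted p up to 0.13, 0.12 and 0.071). Rises in the NF-kB list numbered 6, 6 and 6 without BP 1, 2 and 3, and 13, 6 and 19 without BP+Huaier 1, 2 and 3, and 3 members fell without BP+Huaier 3.

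Among hypoxia and glycolysis genes VEGFA, ALDOC and PFKFB3 rose 2.66-fold, 2.61-fold and 2.12-fold. There 12 of 36 rose and 2, PFKFB4 and PDK1, fell (13 and 2 adjusted over the list alone; camera median 0.40, adjusted p = 7.9e-04; adjusted p = 0.31 with an estimated correlation). In the list of epithelial-mesenchymal transition and matrix genes SNAI1, a repressor of epithelial genes, rose 6.55-fold, from 6.41 ± 0.98 to 42.0 ± 18.0 CPM (SD, n = 3), CCN1 rose 3.63-fold and PLAUR rose 3.17-fold. The epithelial genes KRT19 and KRT18 rose in the same list by 2.05-fold and 1.71-fold, so its rises were on both sides of that transition. There 10 of 26 rose and 2, TJP1 and FN1, fell (10 and 2 adjusted over the list alone; camera median 0.22, adjusted p = 0.0012; adjusted p = 0.23 with an estimated correlation). Of 9 targets of the aryl hydrocarbon receptor 4 rose, TIPARP 2.48-fold, CYP1A1 2.36-fold, SLC7A5 2.33-fold and NQO1 1.86-fold (4 adjusted over the list alone; camera median 0.72, adjusted p = 0.0022; adjusted p = 0.16 with an estimated correlation). SLC7A5 is also a member of the integrated stress response list. Lists can thus share members, and their calls are not independent. The NQO1 call was lost without BP 1, 2 or 3 (edgeR adjusted p = 0.053, 0.054 and 0.052), the PFKFB4 and KRT19 calls without each BP library and without BP+Huaier 2 (up to 0.17 and 0.082), the PDK1 call without BP 1, BP 2 or BP+Huaier 2 (up to 0.061), and the TJP1 and KRT18 calls without every library but BP+Huaier 3 (up to 0.12 and 0.13). Rises in the hypoxia and glycolysis list numbered 4, 5 and 6 without BP 1, 2 and 3, and 9, 4 and 24 without BP+Huaier 1, 2 and 3, and 4 members fell without BP+Huaier 3. Falls in the matrix gene list numbered 5 without BP+Huaier 3.

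In total 16 of the 22 pathway lists were called higher and 1 lower by camera with a preset correlation of 0.01. With an estimated correlation 0 were called, and 6 had an unadjusted p under 0.05, while fry called 19, all but heat shock, oxidative phosphorylation and ribosome biogenesis. The 17 lists were also called after the GC and length trend was removed and without BP+Huaier 3, where 4793 lower genes were called in all. Metallothionein and zinc genes were not called (5 of 8 rose and 1, SLC39A10, fell, also adjusted over the list alone; camera median 0.58, adjusted p = 0.063; adjusted p = 0.30 with an estimated correlation). They were called higher with limma-voom (camera adjusted p = 0.025), with no filter on low counts (0.014) and by fry (0.037), in a range of 0.014 to 0.30 over 18 alternatives, and rises numbered 0, 1 and 0 without BP 1, 2 and 3, and 4, 2 and 7 without BP+Huaier 1, 2 and 3. Nuclear genes of oxidative phosphorylation were not called either (NDUFS7 rose and NDUFC2 fell among 76, 0 adjusted over the list alone; camera median 0.18, adjusted p = 0.095). They were called higher without BP+Huaier 3, where 40 members were called higher and 4 lower (camera adjusted p = 8.8e-04), without BP 3 (0.036) and with no filter on low counts (0.0016), in a range of 8.8e-04 to 0.74 over 18 alternatives. After the GC and length trend was removed 9 of the 76 rose and 4 fell by edgeR. For ribosome biogenesis, with 5 of 40 higher and 2, POLR1A and UTP20, lower (4 and 2 adjusted over the list alone), the camera adjusted p was 0.26, and 0.025 with no filter on low counts, in a range of 0.025 to 0.97 over 18 alternatives. Rises numbered 0, 0 and 1 without BP 1, 2 and 3, and 1, 1 and 16 without BP+Huaier 1, 2 and 3, and falls 0, 1 and 0, and 2, 0 and 6, in the same order. The calls of NDUFS7 and NDUFC2 were lost without every library but BP+Huaier 3.

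Markers of other cell types and of RNA quality formed their own family of 9 lists, of which none was called by camera or fry. Cytosolic ribosomal protein genes had a median of 0.23 with 0 of 56 called by edgeR (camera adjusted p = 0.11). They were called higher without BP+Huaier 3, where 42 members were called (camera adjusted p = 1.0e-05), without BP 3 (0.037), with limma-voom (0.032) and with no filter on low counts (3.7e-04), in a range of 1.0e-05 to 0.78 over 18 alternatives. Of 5 ductal markers KRT19 and KRT18 rose and MUC1 fell (camera adjusted p = 0.59, and 0.018 without BP+Huaier 3, where 4 rose). Of 6 fibroblast markers COL1A1 rose and COL5A1 fell, with a median of -0.0016 and a mean of 0.20, which differed in sign. Of 3 kidney epithelial markers CUBN fell 2.08-fold, from 280 ± 6.91 to 135 ± 15.2 CPM (SD, n = 3), and the median of 0.32 and the mean of -0.09 differed in sign. Of 4 endothelial markers ESAM rose and CDH5 fell, with 2 rises without BP+Huaier 3, and CEL fell as the only measured acinar or islet marker. Of 3 immune markers 0 passed (camera adjusted p = 0.59), CD14 being at 42.5 ± 2.55 and 28.8 ± 6.87 CPM, and 1 fell without BP+Huaier 1 or without BP+Huaier 3. Among 12 histone genes H1-2 rose and H2AC11 fell (camera adjusted p = 0.94, with a direction that turned when scaled by library size alone). The mitochondrially encoded genes were listed at 0 in all 6 libraries, and whether the mitochondrial genome was part of the alignment reference is not given in the sources used here, so that no level or limit can be read from them. The calls of KRT18 and COL5A1 were lost without every library but BP+Huaier 3 (edgeR adjusted p up to 0.13 and 0.14), and those of KRT19 and CDH5 without each BP library and without BP+Huaier 2 (up to 0.082 and 0.13). The calls of MUC1, CEL, H1-2 and H2AC11 were each lost without at least 2 libraries (up to 0.069, 0.074, 0.12 and 0.18).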

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

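Where no cause is named, the cause was not tested; removal of the GC and length trend was tested only after the data were seen. No gene called in BP+Huaier against BP was called with the opposite sign under any refit (0 in each), of 2160 higher, 2246 lower and 2014 past 2-fold. With scaling by library size alone 1051 genes were higher. With genes of at least 5 CPM, where fewer genes enter, 1373 were lower and 866 passed 2-fold. At an adjusted p under 0.01, a stricter threshold, 826 were higher and 810 lower. With 1 library left out, higher genes ranged from 810 to 4452, lower genes from 909 to 4793 and genes past 2-fold from 1285 to 3542, lowest without BP 1 or BP 2 and highest without BP+Huaier 3. Fewer libraries lower the power, and leaving out BP+Huaier 3 lowered the spread within its group.

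No pairing by replicate number was seen, though paired cultures are not excluded. Deviations from the mean of 3 libraries depend on each other, and the libraries also differed in GC trend. Same-numbered libraries correlated at r = 0.01, -0.06 and -0.28 in their deviations from the group means, across genes, while BP 3 with BP+Huaier 1 gave 0.26. With the replicate number as a block, 1357 genes were higher, 1742 lower and 1838 past 2-fold, the camera adjusted p of the mitophagy list was 0.23, and no pathway list changed its call, while PINK1 reached an edgeR adjusted p of 0.052 and the fold of FOS was 8.06.

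The autophagy core list passed with no filter on low counts (camera adjusted p = 0.0030), after the GC and length trend was removed (0.039) and by fry (0.0099), and ranged from 0.040 to 0.32 with 1 library left out. The mitophagy list passed with no filter (0.023) and by fry (0.032). Of the other 20 pathway lists, 17 were called, and 0 with an estimated correlation. Lists that were not called turned direction: fibroblast markers with genes of at least 5 CPM (0.55) and members of at least 5 CPM (0.72), endothelial markers after the GC and length trend was removed (0.98), and histones with library size alone (0.91), no filter (0.81), genes of at least 5 CPM (0.96), members of at least 5 CPM (0.72) and 1 library left out (0.52 to 0.93, turned without BP 1, BP+Huaier 1 or BP+Huaier 3). BNIP3L, not called, went to a log2 fold change of 0.0197 after the GC and length trend was removed. The depth of these libraries sets 3 counts at 0.160 to 0.222 CPM, and values below that rest on fewer counts.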

Other observations

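The zinc finger set, the transcript classes, removal of the GC and length trend, the bounds set for the immediate early list, and the tests on BP+Huaier 3 and on the nuclear copies were chosen only after the result was seen. Of 460 measured protein-coding genes with a ZNF, ZFP, ZKSCAN or ZSCAN symbol, which include some that are not transcription factors, such as ZFP36, 151 fell, 34 rose and 275 did not pass (edgeR), so that 32.8% fell against 15.0% of all tested genes. Their median log2 fold change was -0.48 (camera p = 5.9e-07, and p = 0.27 with an estimated correlation). Their transcripts had a median GC content of 44.0%. After the GC and length trend was removed, 178 fell and 48 rose, 38.7% falling against 19.1% of all tested genes (camera p = 5.5e-06, and p = 0.26 with an estimated correlation). With scaling by library size alone 163 fell and 17 rose, 35.4% falling against 19.7%, and without BP+Huaier 3 there were 273 falls and 57 rises, 59.1% against 31.0%. The shares of all tested genes include genes outside the protein-coding class, of which 646 fell and 95 rose in the main fit. Among protein-coding genes, the like background, 1600 of 12459 fell there.

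Some classes of transcript outside protein-coding genes took a smaller share of all counts in BP+Huaier. Over all classes, genes with any count numbered 20575, 21024 and 23582 in BP+Huaier 1, 2 and 3. In BP 1, 2 and 3 they numbered 25193, 25493 and 24675. Long intergenic non-coding RNAs summed to 4604 ± 151 CPM in BP and 3312 ± 893 CPM in BP+Huaier (SD, n = 3), antisense RNAs to 3407 ± 75.4 and 2219 ± 476 CPM, and unprocessed pseudogenes to 1414 ± 30.6 and 621 ± 258 CPM. MTATP6P1, a copy of mitochondrial DNA, made up 77.3% of the last fall, and without it the sums were 455 ± 22.2 and 275 ± 83.7 CPM. In each of these classes, and without MTATP6P1, the 3 BP+Huaier libraries lay below the 3 BP libraries (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). With TMM scaling the same held for antisense RNAs and unprocessed pseudogenes, with and without MTATP6P1, but the long intergenic RNAs overlapped between the groups, at 4204 ± 96.5 and 3583 ± 532 CPM (exact permutation p = 0.2). Processed pseudogenes (1767 ± 115 and 1434 ± 65.2 CPM) and transcribed unprocessed pseudogenes (1490 ± 30.9 and 1089 ± 285 CPM) were also lower as shares of all counts. With TMM scaling these 2 classes overlapped between the groups as well (exact permutation p = 0.7 and 0.3). The GENCODE class TEC was lower under both scalings, at 302 ± 14.0 and 185 ± 66.8 CPM as shares of all counts (exact permutation p = 0.1 in both). As shares of all counts, processed transcripts, sense intronic transcripts and snoRNAs were not lower in every BP+Huaier library. There BP+Huaier 3, at 2648, 310.5 and 51.2 CPM, lay above every BP library (exact permutation p = 0.4, 0.4 and 0.7).

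The immediate early list rose by a median log2 fold change of 1.87. Removal of the GC and length trend left a median of 1.61 with 28 of 29 genes higher, and scaling by library size alone left 1.57 with 26 of 29 higher, while the median of all genes lay at -0.28, which argues against either as the whole cause. A response to Huaier stays open as a hypothesis, as does a change of medium or handling before harvest, which was not tested.

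BP+Huaier 3 lay between the groups, 52.2% of the way from the BP libraries to the other BP+Huaier libraries on the first component. In BP+Huaier 1 and 2, 80 genes rose and 76 fell at least 4-fold, and pooled they need a share of 46.9% BP RNA. In BP+Huaier 3 the risen genes lay at a median of 45.4% of the way and the fallen genes at 66.9%. Admixed RNA of a BP culture at the pooled share would set a floor for fallen genes, but 25 of the 76 (32.9%) lay below it. The fallen genes helped to set that share, and alone they need a smaller one than the risen genes. After the GC and length trend was removed BP+Huaier 3 lay 59.7% of the way on the first component, which argues against that trend. The highest BP library lay 3.65% of the way before removal, so no partner for a swap was seen. A weaker or shorter response, a smaller share of BP RNA and a mixture with a culture that responded differently stay open.

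Counts on nuclear copies of mitochondrial DNA fell. Summed over 404 copies they were 1063 ± 21.1 CPM in BP and 394 ± 191 CPM in BP+Huaier (SD, n = 3; 971 ± 13.4 and 420 ± 150 with TMM scaling), mostly on MTATP6P1 (ENSG00000248527.1, GRCh38 chromosome 1, 633696 to 634376; log2 fold change -1.25 ± 0.24, SE, edgeR adjusted p = 0.0068). Nuclear genomic DNA at the rate per kilobase of 381 olfactory receptor genes (1.63 ± 0.53 CPM in BP and 0.36 ± 0.31 CPM in BP+Huaier, SD, n = 3) would bring, at its upper 95% counting limit, 0.103% of the fall of all copies and 1.23% of that of the copies other than MTATP6P1, which argues against it. Of the 404 copies 10 were tested, of which 5 were called lower and 0 higher. These 5 lie close together on chromosome 1, between 629062 and 634922, so they are not independent loci. They were 98.2% to 99.1% identical to mitochondrial transcripts over the aligned bases. Of the copies not called, MTCYBP21 and MTND5P1 on chromosome 21 had log2 fold changes of 0.28 and 0.19. Their identity was lower, 67.7% and 72.6%, the latter over 164 aligned bases. The others, MTND4P12, MTCO2P12 and MTND5P11, had negative changes and were 95.8%, 98.0% and 93.0% identical. Whether direction follows identity was not tested. All 5 copies called lower were also called lower after the GC and length trend was removed, which argues against that trend for this stretch. Mitochondrial DNA was not tested. MTATP6P1 is 98.5% identical to the mitochondrial transcript MT-ATP6, and the mitochondrial genes themselves were listed at 0, with no source saying whether their genome was aligned to, so a fall of mitochondrial transcripts and a fall of the copies cannot be told apart.

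For the 4406 genes called between the groups, 1 of the 10 splits of the 6 libraries, the real one, gave as many calls, and the highest of the others gave 0 by edgeR, with 10 to 2178 genes at an unadjusted p under 0.05 against 6498. These splits are too few for a share under 0.05.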
